A study of Rattus norvegicus with 16 samples.

How the data were processed

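Gene expression was measured in 16 diencephalons, each from 1 male Sprague-Dawley rat, with 1 Affymetrix rat expression array per rat and 4 arrays in each of 4 groups. The diencephalon is the part of the brain that holds the thalamus and the hypothalamus. Total RNA had been amplified and labelled by a method primed at the 3 prime end of transcripts. Rats entered at 5 weeks of age. In the 10-day experiment, zinc-deficient rats (ZD) ate a diet with 0.6 mg zinc per kg, and pair-fed rats (PF) received the same amount of a diet with 30 mg zinc per kg. In the 16-day experiment, the recovery rats (ZR) spent the first 10 days on the zinc-deficient diet and their pair-fed controls (ZRPF) on the control diet, after which both had 6 days on a fixed ration of 13 g of the control diet. Each experiment began with 9 rats on the zinc-deficient diet and 6 pair-fed rats. The rats put on arrays had been picked by the submitters as average in weight, plasma zinc and salt preference, so their spread is not that of all rats in a group. The salt test used 300 mM NaCl in all 4 groups, and salt intake was not part of the fit.

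The deposited values were linear signal intensities, 1 per probe set and array, which the authors had made with MAS5 (its version was not given in the sources used here). In every array the mean signal without the top and bottom 2% of probe sets was 500.13 to 500.15. The table held 31099 probe sets, of which 57 controls were set aside for checks of labelling and RNA integrity. Signals were taken as log2 without further normalization. For arrays, the number of rats limits the precision of each value. The median signal per array ranged from 157 to 173.

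Probe sets were tested when their mean log2 signal over all 16 arrays was at or above the median over probe sets (7.35, a signal of 163), which left 15521. Gene names came from the platform annotation joined by gene identifier to a current rat gene table. A single gene was listed for 20826 probe sets, several for 436 and none for 9780. Probe sets with several genes or none were tested but not named. Where lists of genes were tested, each gene was represented by its brightest tested probe set, which gave 9278 genes.

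The 4 groups were fitted together with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step. Contrasts were ZD against PF, ZR against ZRPF, the difference between these changes (the interaction), and ZRPF against PF. Fold changes are given with standard errors from this fit, group means with standard deviations. P values were two-sided and adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. Rat numbers were not used as pairs, since equal numbers in different groups were read as unrelated rats. Correlations of deviations between PF and ZRPF rats of the same number were 0.079, 0.020 and 0.035. Between PF and ZRPF rats of unlike number they ran from -0.034 to 0.052.

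Gene lists for zinc handling, feeding and salt balance, hormone and stress responses, metabolism, cell types and neighbouring brain regions were fixed before the data were examined, 36 in all. With at least 3 tested members required, 34 were tested with camera at a preset correlation of 0.01, adjusted over the lists. Beside it stand camera with the correlation estimated from the residuals, fry, which tests whether the genes of a list moved on balance one way without comparing them with other genes, and an exact permutation test of the list mean per array, whose smallest two-sided p with 4 against 4 arrays is 0.0286. Tests of the lists on the interaction contrast, exact tests of list means, the contrast averaging both experiments, and the fate of the 100 genes of smallest p were added after the data were seen.

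Genes named in the text followed a rule fixed before the data were examined: up to 12 genes in each direction for ZD against PF and for ZR against ZRPF, and up to 6 for the other contrasts, by smallest p among those past the threshold, with the next smallest p filling up to 6 and reported as not past it. To these came a fixed set of zinc, feeding, salt and marker genes, and up to 4 members of each list by size of statistic. Genes named outside this rule are said to be so where they appear.

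The pipeline was tested on simulated data of the same size. In these, 49 of 67 probe sets with a log2 change of 0.5 were recovered, as were 67 of 67 with a change of 1 and 66 of 66 with a change of 2, with 8 false calls among 190. No list was called without a simulated shift, whereas other splits of the real ZD and PF arrays called a median of 6 lists, so the simulation does not give the rate of false list calls. The simulated noise was independent between probe sets, so the shares recovered are not those of the real arrays either.

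Alternatives tried were quantile normalization, median centring, no filter, only the brightest 10348 probe sets, an offset of 32 before the log, no intensity trend, array weights, covariates for choroid plexus and thalamus content and for the 3 prime to 5 prime ratio of Gapdh, probe sets averaged per gene, each comparison fitted on its own 8 arrays, each array left out in turn, and rat number as a block for ZRPF and PF. Added after the data were seen were leaving out ZD arrays 8 and 9 together, and the covariates (with that of beta-actin) for the lists. No array was left out of the values reported.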

Results

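The data were signal intensities of 31099 probe sets in the diencephalon of 16 rats. Groups of 4 rats each were zinc-deficient (ZD) or pair-fed (PF) for 10 days, or had 6 further days of zinc after deficiency (ZR) or after pair-feeding (ZRPF). Signals correlated at 0.974 to 0.987 between arrays of one group and at 0.952 to 0.972 between arrays of different experiments. The first principal component held 35.1% of the variance and separated the 10-day from the 16-day arrays.

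What 10 days of zinc deficiency did beyond reduced food intake was addressed by ZD against PF, in which no single gene passed the threshold. The genes with the smallest p included *Npy1r*, the Y1 receptor of the feeding peptide neuropeptide Y, with a log2 signal of 10.03 ± 0.14 (SD, n = 4) in PF and 9.44 ± 0.29 in ZD. *Gpd1*, the cytosolic glycerol-3-phosphate dehydrogenase, had 12.53 ± 0.38 in PF and 11.53 ± 0.32 in ZD, and *Cryab*, a small heat shock protein, had 12.08 ± 0.42 and 11.22 ± 0.20. Among genes with higher signals, *Tagln*, an actin-binding protein of smooth muscle, differed by a log2 fold change of 0.91 ± 0.17 (SE), *Nr1d1*, a repressor of the circadian clock, by 0.71 ± 0.15 and *Cdh15*, a cadherin, by 0.64 ± 0.12. *Serping1*, the complement C1 inhibitor, stood at 0.64 ± 0.13, *Tbc1d13*, a Rab GTPase-activating protein, at 0.56 ± 0.11 and *Lyz2*, the lysozyme of myeloid cells, at 0.45 ± 0.09. On the lower side *Lrrn3*, a leucine-rich repeat protein of neurons, stood at -0.55 ± 0.09, *Tra2a*, a splicing factor, at -0.40 ± 0.08 and *Lyrm2*, a mitochondrial protein, at -0.38 ± 0.08. Each of these 12 genes had an adjusted p of 0.151, and for *Lyrm2* a second probe set stood at 0.18 ± 0.12. In *Npy1r* the groups overlapped, and for each of the other 11 all 4 ZD arrays lay on one side of all 4 PF arrays.

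None of the 15521 probe sets passed in limma, while 1220 had an unadjusted p under 0.05 where 776 are expected by chance and regroupings of the same 8 arrays gave up to 1392. Of 9278 genes, 404 (4.35%) had ZD and PF arrays without overlap, and chance gives 2.86%. Without ZD array 8, 3 probe sets passed: *Npy1r* (-0.73), *Lrrn3* (-0.61) and one with no gene listed (0.89). With ZD arrays 8 and 9 both left out, 1 passed, that of *Csrnp3* (1.34), a gene outside the naming rule and named after its value was seen.

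Among genes of zinc handling, the smallest p between ZD and PF was that of the importer *Slc39a10*, whose log2 signal was 11.19 ± 0.09 in PF and 11.44 ± 0.08 in ZD, higher in 4 of 4 ZD arrays. Its adjusted p over all probe sets was 0.265, and it was the 1 of 14 tested zinc transporters that passed when adjusted over the list alone. The next zinc transporters were *Slc39a7* (0.43 ± 0.16), *Slc39a11* (0.12 ± 0.10) and *Slc39a3* (-0.16 ± 0.13, with 0.50 ± 0.20 on its second probe set), and the list as a whole did not pass (adjusted p = 0.521). The list of metallothioneins, the zinc-binding proteins, and MTF1 did not pass either (adjusted p = 0.813). Its 4 tested members included *Mtf1* and *Mtf2*, which are not metallothioneins. Of the metallothioneins, *Mt2A* stood at -0.22 ± 0.19 and *Mt3* at 0.05 ± 0.10. Mt1 and *Slc30a1* lay below the filter.

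Of the feeding peptides none passed between ZD and PF, over all genes or adjusted over the list alone. *Cartpt*, an appetite-reducing peptide, stood at 0.32 ± 0.13, *Gal* at -0.31 ± 0.14, *Nucb2* at 0.27 ± 0.13 and *Bdnf* at -0.28 ± 0.13. Nearer to 0 were *Npy* at 0.04 ± 0.11, *Hcrt* at 0.07 ± 0.09, *Pmch* at 0.02 ± 0.07, *Trh* at -0.03 ± 0.11 and *Crh* at -0.05 ± 0.12. For *Npy*, array ZD 8 had a log2 signal of 10.00 and the other ZD arrays 10.48 to 10.57. The list did not pass (adjusted p = 0.681). *Oxt* and *Avp*, the hormones of the neurohypophysis, stood at -0.54 ± 0.23 and -0.34 ± 0.29. Array ZD 8 held their lowest log2 signals (10.91 and 9.93), and without it *Avp* stood at 0.09 and *Oxt* at -0.27. *Pomc* lay below the filter and *Agrp* was not analysed here.

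By camera with the preset correlation, 11 of 34 gene lists passed between ZD and PF, and none of the 11 with an estimated correlation. Glucocorticoid targets, which stress hormones induce, were lower in ZD in 18 of 18 tested members, by a mean log2 change of -0.39 (adjusted p = 2.55e-09). The list had an adjusted p = 0.243 with an estimated correlation. Members included *Pdk4* (-1.08 ± 0.41), *Arrdc2* (-0.54 ± 0.17), *Bcl6* (-0.40 ± 0.15), *Tsc22d3* (-0.26 ± 0.10) and *Fkbp5* (-0.14 ± 0.21). In limma 0 of 18 passed over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05. The list mean per array was 0.17 ± 0.26 in PF and -0.22 ± 0.21 in ZD, an exact two-sided permutation p of 0.0857. With ZD arrays 8 and 9 both left out the mean change was -0.22 (adjusted p = 0.00138).

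Heat shock genes, chaperones induced by misfolded protein, were lower in ZD in 19 of 19 members, by a mean of -0.19 (adjusted p = 6.91e-08, and adjusted p = 0.243 with an estimated correlation). *Cryab* and *Chordc1* (-0.41 ± 0.12) passed when adjusted over the list alone, and *Stip1* (-0.25 ± 0.09) and *Dnaja1* (-0.18 ± 0.07) did not. In the unfolded protein and amino acid response list, 21 of 25 members were lower, by a mean of -0.10 (adjusted p = 0.000548, and adjusted p = 0.257 with an estimated correlation). Adjusted over the list alone, 3 members passed as lower and 2 as higher. The endoplasmic reticulum chaperones *Sdf2l1* (-0.60 ± 0.16), *Hspa5* (-0.38 ± 0.11) and *Manf* (-0.35 ± 0.11) stood on the lower side, and *Phgdh* (0.25 ± 0.08), an enzyme of serine synthesis, on the higher. Cholesterol synthesis genes were higher in 16 of 19 members, by a mean of 0.11 (adjusted p = 0.00335, and adjusted p = 0.311 with an estimated correlation). Of *Dhcr7* (0.42 ± 0.11), *Insig1* (0.31 ± 0.09), *Hsd17b7* (0.22 ± 0.10) and *Srebf2* (0.17 ± 0.08), the former 2 passed adjusted over the list alone. Without ZD arrays 8 and 9 the cholesterol list stood at 0.08 and no longer passed (adjusted p = 0.133).

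Markers of tissue that borders or vascularises the diencephalon were higher in ZD. Choroid plexus markers were higher in 9 of 9 members, by a mean of 0.77 (adjusted p = 0.00335, and adjusted p = 0.517 with an estimated correlation). Single markers were *Ttr* at 3.15 ± 1.28, *Slc13a4* at 0.91 ± 0.43, *Slc22a8* at 0.49 ± 0.14 and *Igfbp2* at 0.49 ± 0.25. The signal of *Ttr*, the transthyretin of the choroid plexus, ran from 209 to 1323 in PF and from 905 to 9928 in ZD. This list was no longer past the threshold without ZD array 3 (mean 0.60, adjusted p = 0.0743), and its mean was 0.48 with no filter (adjusted p = 0.0471). Meningeal and mural cell markers were higher in 14 of 15 members, by a mean of 0.37 (adjusted p = 4.84e-06, and adjusted p = 0.257 with an estimated correlation). They included *Tagln*, *Col1a1* (0.52 ± 0.18), *Mgp* (0.37 ± 0.15) and *Vtn* (0.31 ± 0.11). Their mean was 0.23 without ZD array 8 (adjusted p = 0.0111).

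Of further cell types, microglia markers were higher in 9 of 13 members by a mean of 0.15 (adjusted p = 0.0187, and adjusted p = 0.457 with an estimated correlation), led by *Lyz2*, *P2ry12* (0.36 ± 0.14), *Aif1* (0.30 ± 0.13) and *Csf1r* (0.26 ± 0.12). Endothelial markers were higher in 15 of 17 members by a mean of 0.14 (adjusted p = 0.0236, and adjusted p = 0.299 with an estimated correlation), with *Vwf* at 0.49 ± 0.14, *Abcb1a* at 0.63 ± 0.29 (and -0.15 ± 0.21 on its second probe set), *Flt1* at 0.34 ± 0.17 and *Slc16a1* at 0.10 ± 0.06. Ependyma and tanycyte markers were higher in 8 of 9 members by a mean of 0.20 (adjusted p = 0.034, and adjusted p = 0.243 with an estimated correlation), with *Vim* at 0.40 ± 0.10 and *Foxj1* at 0.61 ± 0.28. Fry gave this list an adjusted p of 0.00159, the only list to pass by fry. Interferon and MHC genes were higher in 8 of 10 members by a mean of 0.23 (adjusted p = 0.034, and adjusted p = 0.452 with an estimated correlation), with *Cd74* at 0.68 ± 0.27, *Ifitm3* at 0.52 ± 0.20, *Irf1* at 0.41 ± 0.16 and *Irf7* at 0.29 ± 0.24. For *Irf7*, array ZD 2 had a log2 signal of 8.69 and the other ZD arrays 7.66 to 7.69. Thalamus markers were lower in 14 of 19 members by a mean of -0.10 (adjusted p = 0.00321, and adjusted p = 0.452 with an estimated correlation), with *Shox2* at -0.39 ± 0.19, *Vav3* at -0.27 ± 0.10, *Synpo2* at -0.25 ± 0.10 and *Ntng1* at -0.19 ± 0.10.

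Leaving out single arrays ended several of these calls. The microglia list lost its call without PF array 2 (mean 0.08, adjusted p = 0.395) or ZD array 2 (0.09, 0.231), and the thalamus list without ZD array 2 (-0.06, 0.125) or PF array 6 (-0.06, 0.0524). The endothelial list, whose mean stayed between 0.11 and 0.18, lost it without PF array 2 (0.116), PF array 6 (0.0846), ZD array 2 (0.129), ZD array 3 (0.0559) or ZD array 8 (0.146), and the interferon list without PF array 2 (mean 0.16, 0.281), PF array 6 (0.20, 0.0846), ZD array 2 (0.13, 0.386) or ZD array 3 (0.25, 0.0637). For the ependyma list, whose mean stayed between 0.17 and 0.23, the arrays were PF 1 (0.0586), PF 6 (0.0524), ZD 3 (0.0817) and ZD 8 (0.0839), and with no filter its mean was 0.01 (adjusted p = 0.407). Quantile normalization ended the calls of the interferon (mean 0.21, 0.0508) and ependyma (0.17, 0.0706) lists. Without ZD arrays 8 and 9 the ependyma list did not pass (0.0586), while the interferon mean was 0.36 (0.00118) and the thalamus mean -0.17 (2.45e-05). With choroid plexus and thalamus content as covariates the microglia (adjusted p = 0.289), endothelial (0.148), interferon (0.148) and ependyma (0.148) lists did not pass. Their means were then 0.08 for microglia, 0.12 for endothelial, 0.20 for interferon and 0.18 for ependyma genes.

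**Figure D1:**
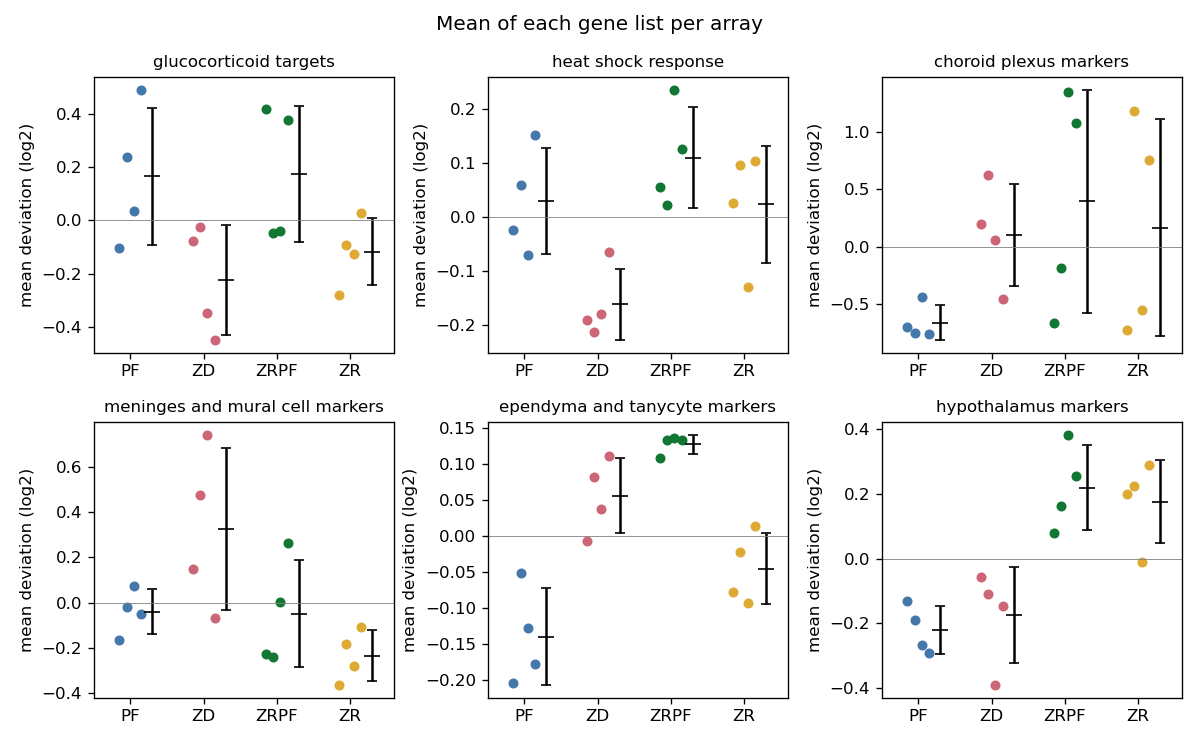
Mean log2 deviation of the tested members of 6 gene lists from their mean over all arrays, by group, with 1 point per array (n = 4) and the group mean ± SD beside it in black. In the ZD group the glucocorticoid mean was -0.22 against 0.17 in PF, and the choroid plexus mean was 0.10 against -0.67.

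Whether differences remained 6 days after zinc was returned was addressed by ZR against ZRPF, in which 1 of 15521 probe sets passed in limma, that of *Clstn3*, a calsyntenin of synaptic membranes. Its log2 signal was 9.40 ± 0.38 (SD, n = 4) in ZRPF and 7.69 ± 0.45 in ZR, a log2 fold change of -1.71 ± 0.26 (SE, adjusted p = 0.046), lower in 4 of 4 ZR arrays. In PF and ZD it was 7.98 ± 0.34 and 8.15 ± 0.52. Over 18 alternatives its adjusted p ran from 0.0196 to 0.345, and 7 kept it past the threshold, while its log2 fold change stayed between -1.89 and -1.54. The call ended without ZRPF array 2 (adjusted p = 0.345), 4 (0.268) or 5 (0.0501), without ZR array 7 (0.296), 10 (0.314) or 15 (0.136), and with quantile normalization (0.054), no filter (0.0913), no intensity trend (0.121), the Gapdh covariate (0.085) or its own 8 arrays (0.098).

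Other genes of smallest p in ZR against ZRPF did not pass (adjusted p = 0.927 for each). *Ogfrl1* stood at -0.47 ± 0.10, *Vps39*, a component of lysosomal tethering, at -0.40 ± 0.09, *Pdcd11*, a ribosomal RNA processing factor, at -0.39 ± 0.09. Further lower values were those of *Adipor2*, an adiponectin receptor, at -0.50 ± 0.13, and *Galnt1*, an enzyme of O-glycosylation, at -0.34 ± 0.09. On the higher side were *Ambra1*, a regulator of autophagy, at 0.74 ± 0.18, *Pspc1*, a paraspeckle component, at 0.58 ± 0.14, and *Pnn*, a splicing protein, at 0.57 ± 0.15. Also higher were *RT1-S3*, an MHC class I gene, at 0.75 ± 0.19, *Chd8*, a chromatin remodeller, at 0.34 ± 0.09 and *Cfdp1* at 0.26 ± 0.07. Other probe sets stood at -0.14 ± 0.17 for *Adipor2*, -0.25 ± 0.16 for *Galnt1* and 0.72 ± 0.22 for *Pnn*. Unadjusted p was under 0.05 for 808 probe sets where 776 are expected by chance, and 262 of 9278 genes (2.82%) had groups without overlap, where chance gives 2.86%. Without ZRPF array 6, 9 probe sets passed, among them those of *Clstn3*, *Ambra1* (0.94) and *Pspc1* (0.74).

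After recovery *Slc39a10* stood at 0.00 ± 0.06, *Npy* at -0.16 ± 0.11, *Cartpt* at -0.07 ± 0.13, *Mt2A* at -0.08 ± 0.19, *Oxt* at -0.28 ± 0.23 and *Avp* at -0.24 ± 0.29. The zinc transporter list had an adjusted p of 0.22, with *Slc39a7* at 0.49 ± 0.16 and *Slc39a1* at 0.27 ± 0.09. The feeding peptides (adjusted p = 0.918) and the list of metallothioneins and MTF1 (adjusted p = 0.752) did not pass. Within these 3 lists no member passed adjusted over the list alone. *Hbb*, a haemoglobin gene that marks blood, stood at -0.58 ± 0.18, with a log2 signal of 10.55 in array ZR 7 and from 11.44 to 11.93 in the other ZR arrays.

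By camera with the preset correlation, 6 lists passed between ZR and ZRPF, all lower in ZR, and none with an estimated correlation. Glucocorticoid targets were again lower in 18 of 18 members, by a mean of -0.29 (adjusted p = 3.03e-06, and adjusted p = 0.785 with an estimated correlation), among them *Fam107a* (-0.29 ± 0.14), *Arrdc2* (-0.36 ± 0.17), *Gjb6* (-0.30 ± 0.14) and *Tsc22d3* (-0.19 ± 0.10). None of the 18 passed adjusted over the list alone, and the list means were 0.18 ± 0.26 in ZRPF and -0.12 ± 0.13 in ZR (exact two-sided permutation p = 0.114). Respiratory chain subunits were lower in 51 of 53 members by a mean of -0.06 (adjusted p = 0.000231, and adjusted p = 0.831 with an estimated correlation), and ribosomal proteins in 21 of 22 by a mean of -0.08 (adjusted p = 0.000335, and adjusted p = 0.831 with an estimated correlation). Examples were *Sdhc* (-0.19 ± 0.07), *Ndufb8* (-0.27 ± 0.12), *Rps15* (-0.17 ± 0.07) and *Rpl4* (-0.14 ± 0.06). The unfolded protein list was lower in 19 of 25 members by a mean of -0.08 (adjusted p = 0.00757, and adjusted p = 0.785 with an estimated correlation), with *Xbp1* at -0.23 ± 0.08, *Creld2* at -0.39 ± 0.14 and *Dnajc3* at -0.28 ± 0.10.

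Astrocyte markers were lower in ZR in 11 of 16 members by a mean of -0.09 (adjusted p = 0.00944, and adjusted p = 0.785 with an estimated correlation), with *Aldh1l1* at -0.26 ± 0.10 and *S100b* at -0.18 ± 0.08. Ependyma and tanycyte markers were lower in 8 of 9 members by a mean of -0.17 (adjusted p = 0.0104, and adjusted p = 0.242 with an estimated correlation). Examples were *Vim* at -0.34 ± 0.10, *Drc12* at -0.34 ± 0.15, *Tekt1* at -0.26 ± 0.15 and *Crym* at -0.40 ± 0.25, and an adjusted p of 0.0034 by fry. Without ZR array 13 the unfolded protein (mean -0.06, adjusted p = 0.165), ribosomal (-0.05, 0.165), astrocyte (-0.07, 0.217) and ependyma (-0.16, 0.105) lists lost their calls. The call was also lost without ZRPF array 4 by the ribosomal (-0.07, 0.0875), astrocyte (-0.09, 0.0934) and ependyma (-0.17, 0.0934) lists, without ZRPF array 2 by the astrocyte list (-0.08, 0.0758), and without ZRPF array 6 by the unfolded protein list (-0.06, 0.0857). Quantile normalization ended the calls of the ribosomal (mean -0.04, 0.127), respiratory chain (-0.04, 0.0603) and astrocyte (-0.07, 0.0752) lists, leaving out the filter that of the ependyma list (mean -0.06, 0.119), and a beta-actin covariate that of the astrocyte list (mean -0.05, 0.29).

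**Figure D2:**
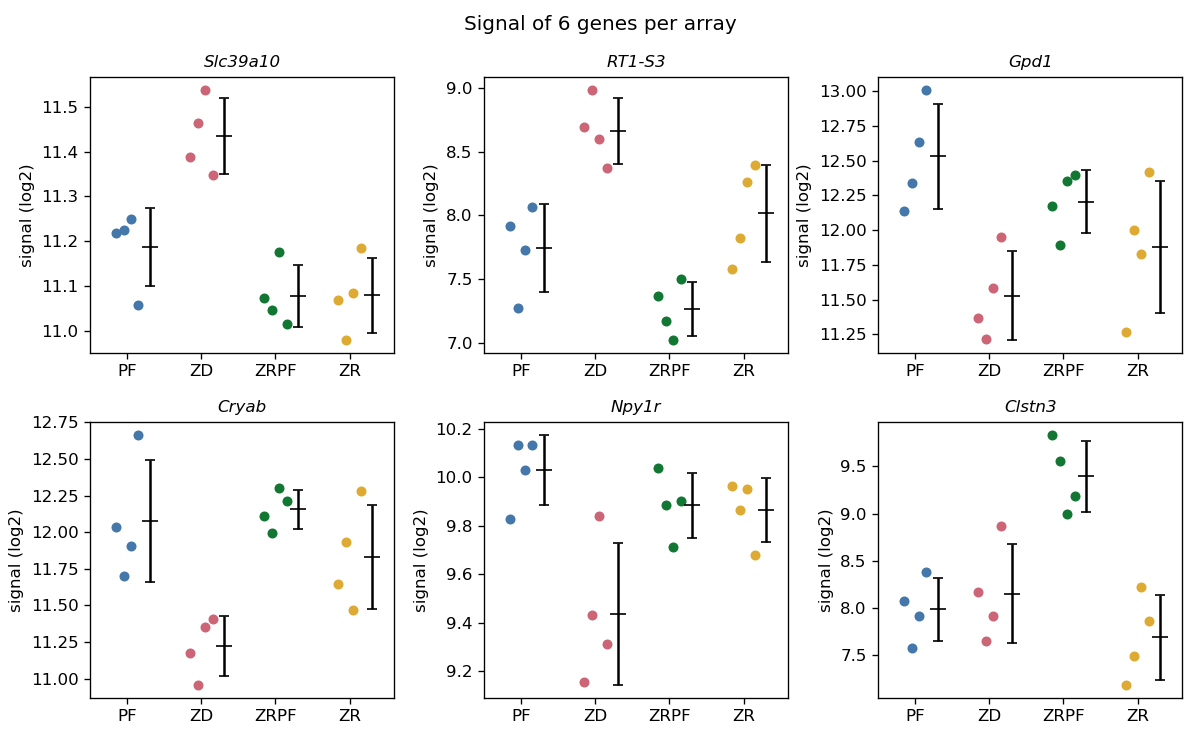
Log2 signal of 6 genes on each array, by group (n = 4), with the group mean ± SD beside the points in black. Slc39a10 lay between 11.35 and 11.54 in ZD and at or below 11.25 in PF, and Clstn3 stood at 7.69 in ZR against 9.40 in ZRPF.

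Whether the change with deficiency differed from that after recovery was addressed by the interaction, in which none of 15521 probe sets passed in limma and 1025 had an unadjusted p under 0.05. The genes of smallest p were *Vim*, an intermediate filament of astroglia and tanycytes, with a difference of changes of 0.74 ± 0.14 (SE) and *Clstn3* with 1.88 ± 0.36 (adjusted p = 0.375 for both). They were followed by *Tbc1d13* (0.76 ± 0.16), *Cdh15* (0.77 ± 0.17), *Tax1bp3* (0.78 ± 0.17) and *Tagln* (1.07 ± 0.25) on the higher side and *Lyrm2* (-0.53 ± 0.11), *Cfdp1* (-0.43 ± 0.10), *Zfp638* (-0.55 ± 0.13), *Tra2a* (-0.50 ± 0.12), *Dpm1* (-0.34 ± 0.09) and *Vwc2* (-0.61 ± 0.16) on the lower. Other probe sets stood at 0.33 ± 0.17 for *Lyrm2*, at -0.05 ± 0.18 and -0.21 ± 0.20 for *Zfp638* and at -0.24 ± 0.17 for *Tra2a*. For *Slc39a10* the difference was 0.25 ± 0.09 (adjusted p = 0.747). One probe set passed without ZD array 9 (*Vim*, 0.84) and 1 without ZRPF array 4 (*Tbc1d13*, 0.89).

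Across 9278 genes the changes of the 2 experiments were close to uncorrelated, with Pearson's r of 0.018 (exact permutation p = 0.914 over 35 splits) and Spearman's rho of -0.031 (exact permutation p = 0.8). Genes are not independent replicates, and these were 2 of 3 relations computed. In the third, the 100 genes of smallest p between ZD and PF, with a median absolute log2 change of 0.41, had a median change of 0.01 between ZR and ZRPF in the direction of their change in ZD (exact permutation p = 0.486). Of the 100, 63 kept their sign, a count that was not tested. That set was chosen after the data were seen.

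**Figure D3:**
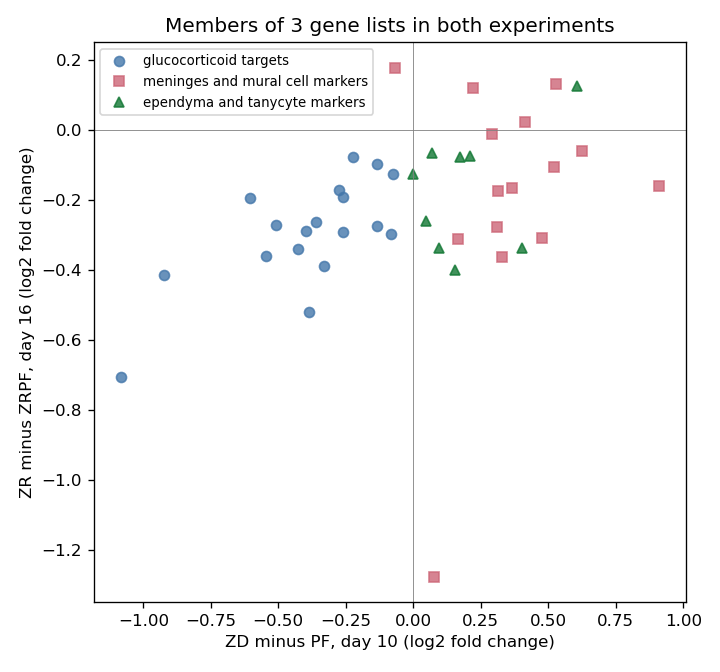
Log2 fold change of each tested member of 3 gene lists between ZD and PF (horizontal axis) and between ZR and ZRPF (vertical axis), 1 point per gene. All 18 glucocorticoid targets lie below 0 on both axes, and 14 of 15 meningeal and mural markers lie above 0 on the horizontal axis.

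The pair-fed groups themselves, ZRPF against PF, differed in day of sampling, age and feeding history, and here 2430 of 15521 probe sets passed in limma, 1475 higher and 955 lower in ZRPF. *Atp1b2*, a subunit of the sodium pump, was higher by a log2 fold change of 0.98 ± 0.07 (SE, adjusted p = 7.72e-08, higher in 4 of 4 arrays), and *Xiap*, a caspase inhibitor, by 2.19 ± 0.15 (adjusted p = 7.72e-08). *Mapre2*, a microtubule end-binding protein, rose by 0.93 ± 0.07, *Zfp74* by 1.44 ± 0.12 and *Npepps*, an aminopeptidase, by 0.71 ± 0.07. *Pals2* rose 2.38-fold on its named probe set, where its 4 other probe sets stood between -0.30 and 0.06. Averaged over its probe sets it stood at 0.16 and did not pass. Lower in ZRPF were *Dync1li1*, a dynein chain (-0.91 ± 0.07, and -0.86 on its second probe set), *Kpna1*, an importin (-1.12 ± 0.09, and -0.43 and -0.09 on others), *Rasal2*, a Ras GTPase-activating protein (-0.73 ± 0.07), *Id2*, an inhibitor of basic helix-loop-helix factors (-0.93 ± 0.11, and -0.19 on its second probe set), *Cmpk1*, a nucleotide kinase (-0.29 ± 0.04), and the sterol demethylase *Cyp51* (-0.46 ± 0.05, and -0.03 on its second probe set). These 12 genes were higher or lower in 4 of 4 ZRPF arrays, with adjusted p of at most 0.000241. With rat number as a block on 6 arrays *Cmpk1* no longer passed (adjusted p = 0.0568).

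Hypothalamus markers were higher in ZRPF than in PF in 9 of 10 members by a mean of 0.44 (adjusted p = 0.00095, and adjusted p = 0.497 with an estimated correlation). *Nnat* (0.77 ± 0.12), *Nkx2-1* (0.74 ± 0.18), *Hap1* (0.55 ± 0.09) and *Sparc* (0.31 ± 0.09) passed over all probe sets, and 7 members passed adjusted over the list alone. Without the filter the mean was 0.23 (adjusted p = 0.0446). Cholesterol synthesis genes were lower in 17 of 19 members by a mean of -0.15 (adjusted p = 0.00554, and adjusted p = 0.775 with an estimated correlation). Over all probe sets *Cyp51*, *Msmo1* (-0.36 ± 0.07), *Nsdhl* (-0.28 ± 0.07) and *Insig1* (-0.37 ± 0.09) fell and *Srebf2*, a regulator of the pathway, rose (0.66 ± 0.08), and adjusted over the list alone 6 members were lower and 1 higher. *Insig1* was named here after its value was seen. Choroid plexus markers were higher in 9 of 9 members by a mean of 1.06 (adjusted p = 0.0452, and adjusted p = 0.917 with an estimated correlation), a call that was lost without PF array 1 (mean 1.05, 0.0524) or 2 (1.03, 0.0719), or ZRPF array 5 (0.74, 0.181) or 6 (0.83, 0.154). *Ttr* signals in the 16-day arrays ran from 327 to 21240.

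Of the neuropeptides, *Hcrt*, the orexin precursor, rose in ZRPF over PF by 0.30 ± 0.09 (adjusted p = 0.0266), as did the metallothionein *Mt3* by 0.32 ± 0.10 (adjusted p = 0.0338), while *Oxt* (0.67 ± 0.23, adjusted p = 0.0502) and *Avp* (0.49 ± 0.29) did not pass. In all, 1993 of 9278 genes (21.5%) had groups without overlap, where chance gives 2.86%. Controls added before labelling differed between the experiments in the same arrays: 8 of 9 such probe sets were 1.60-fold to 3.30-fold higher in the 10-day arrays, and the 5 prime probe set of the bacterial transcript Dap, with signals of 21.3 to 64.7 in the 16-day arrays, 9.19-fold. Of the controls added at hybridization, BioDn was 1.23-fold higher (adjusted p = 0.00486) and Cre 0.837-fold (adjusted p = 0.00753), while BioB (0.329) and BioC (0.28) did not pass. The 3 prime to 5 prime ratio of beta-actin ran from 2.59 to 3.31 in the 10-day and from 4.14 to 5.59 in the 16-day arrays. With a covariate for the like ratio of Gapdh 771 probe sets passed, and with choroid plexus and thalamus content 1465. The Gapdh ratio itself ran from 1.03 to 1.11 in the 10-day and from 1.11 to 1.23 in the 16-day arrays. A covariate that nearly follows the experiment lowers the count whatever the cause, so this does not show that RNA integrity made the calls. Centring each array on its median, which moved the change between these groups by 0.085, turned the balance to 975 higher and 2146 lower.

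**Figure D4:**
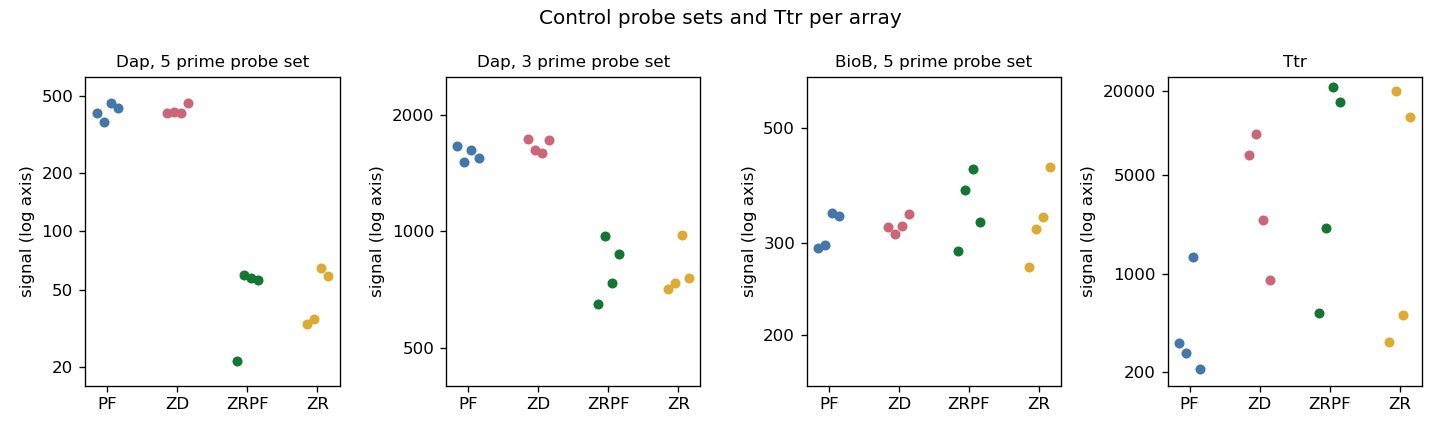
Signal of 3 added control probe sets and of Ttr on each array, by group (n = 4), on log axes. The Dap 5 prime control lay between 366 and 458 in the 10-day groups and between 21.3 and 64.7 in the 16-day groups, and BioB, added at hybridization, between 294 and 343 and between 271 and 420.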

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

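Tests chosen after the result was seen were those of the fasting state, of choroid plexus content within groups and of separate labelling, together with the gene lists on the interaction contrast and the covariates for the lists.

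Glucocorticoid targets were lower in ZD than in PF, a mean log2 change of -0.39 over 18 genes. With choroid plexus and thalamus content as covariates the change was -0.44 ± 0.19 (SE), no smaller than without them. This argues against uneven content of both as its cause only at a margin of 1 SE, so that cause is not excluded. Content of other tissue was not used as a covariate and stays open. Array ZD 8, with a glucocorticoid mean of -0.35, had the lowest hypothalamus mean of all arrays (-0.39) and the highest meningeal mean (0.74). In ZD 9, with a glucocorticoid mean of -0.45, these were -0.15 and -0.07. A difference in the fasting state cannot be told apart: the 18 tested genes of the fasting and insulin list not shared with the glucocorticoid list had a mean change of 0.0061 ± 0.057 (exact permutation p = 0.886), but 9 were higher and 9 lower, so their mean decides nothing. RNA quality cannot be told apart, as the change was -0.33 ± 0.16 with the 3 prime to 5 prime ratio of beta-actin as a covariate, too wide a spread to exclude that it makes up part. An effect of zinc deficiency on corticosterone signalling stays open and untested, as does chance.

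Choroid plexus markers were higher in ZD by a mean log2 of 0.77. Within groups, arrays with more *Ttr* had more of the other choroid plexus markers (r = 0.93, permutation p = 7e-05, adjusted 0.00014; rho = 0.93, permutation p = 0.00089, adjusted 0.00178; r = 0.91 without the 2 farthest arrays), which is consistent with an uneven amount of choroid plexus taken with the tissue. The meningeal and mural markers followed the choroid plexus list less closely within groups (r = 0.58, permutation p = 0.0195, adjusted 0.0195; rho = 0.67, permutation p = 0.014, adjusted 0.014; r = 0.58 without the 2 farthest), so for them the same cause cannot be told apart from others. An effect of zinc deficiency on these tissues was not tested apart from dissection and stays open.

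Many probe sets differed between ZRPF and PF. Among called genes with further tested probe sets, 592 of 949 others (62.4%, exact 95% interval 59.2 to 65.5) moved in the direction of the called one, 105 past the threshold in the same direction and 25 in the opposite one, which is consistent with effects of labelling on single probe sets in part of the calls; dim or unresponsive probe sets would lower that share as well. The sample labels do not say when arrays were labelled, so separate labelling of the experiments is inferred from the added controls. It cannot be told apart from day, age and feeding history, because no group was in both experiments. A different amount of control added would move all probe sets of a transcript alike. Those of Dap were 9.19-fold (5 prime), 3.30-fold (middle) and 2.05-fold (3 prime) higher in the 10-day arrays. For Dap this argues against a different amount alone. For Thr, Phe and Lys the 5 prime and 3 prime folds lay closer (2.10 and 1.93, 2.35 and 1.85, 1.67 and 1.60). A different amount as part of the difference cannot be told apart. The 5 prime Dap control was 9.19-fold higher in the 10-day arrays (3.20 on the log2 scale, a signal outside the measured transcripts). That size rests on dim 16-day signals, with 1.60-fold to 3.30-fold for the other 8, and 9 of 9 such poly-A controls differed between experiments while none did between groups within one. Of 4 controls added at hybridization BioDn and Cre differed between experiments too, by less (1.23-fold and 0.837-fold). Day of sampling and age, which the design names, stay open. Uneven dissection was not tested as a cause of these calls and stays open as well. Choroid plexus (mean log2 change 1.06) and hypothalamus (0.44) markers were higher in ZRPF. With choroid plexus and thalamus content as covariates, 1465 probe sets passed instead of 2430.

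Chance was examined by regrouping the arrays. For ZRPF against PF, 1 of 35 splits gave as many probe sets (2430, the highest other 1), so chance can be excluded for that count. It cannot be excluded for the other counts above 0. Between ZD and PF the count of probe sets was 0, which 35 of 35 splits reach whatever the data (highest other 61), so this tests nothing. At an unadjusted p under 0.05, 5 of 35 gave 1220 or more (highest other 1392), and 8 of 35 gave 11 or more lists (highest other 15, median of the others 6, at least 1 in 35 of 35). What sets the arrays apart in the split with 61 probe sets was not tested. Between ZR and ZRPF 5 of 35 splits gave 1 or more probe sets (real 1, highest other 10) and 11 of 35 gave 6 or more lists (highest other 11, median of the others 3.5, at least 1 in 31 of 35). For the interaction the count was again 0, which 100 of 100 regroupings reach (highest other 3). At an unadjusted p under 0.05, 24 of 100 gave 1025 or more (highest other 1827), and 37 of 100 gave 7 or more lists (highest other 13), and for ZRPF against PF 28 of 35 gave 3 or more lists (highest other 11).

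Lists whose change differed between the experiments, by camera on the interaction with the preset correlation and with no call under an estimated one, were meninges and mural cells (difference of mean log2 changes 0.55, adjusted p = 1e-05), ribosomal proteins (0.12, 0.00145), ependyma and tanycytes (0.37, 0.00153), thalamus (-0.13, 0.00331), respiratory chain (0.081, 0.00615), choroid plexus (1.00, 0.00908) and heat shock (-0.10, 0.0102). Adjusted p with an estimated correlation was 0.0634 for the ependyma list, 0.567 for the meningeal list and 0.839 for the other 5. Leaving out single arrays ended the heat shock call (PF 6, ZD 8, ZRPF 4 or ZR 10; highest adjusted p 0.1; difference -0.06, -0.10, -0.08 and -0.08), the respiratory chain call (PF 4, ZD 9 or ZR 13; 0.415; 0.05, 0.03 and 0.07), the choroid plexus call (ZD 3, ZD 8, ZRPF 5, ZRPF 6, ZR 7 or ZR 13; 0.139; 0.83, 1.01, 0.68, 0.77, 0.70 and 0.76), the ribosomal call (ZR 13; 0.0543; 0.09) and the thalamus call (ZR 7; 0.0636; -0.08). With no filter the choroid plexus (0.60, adjusted p = 0.0886) and ependyma (0.07, 0.0814) calls ended and the ribosomal difference was 0.07.

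In 36 of 684 groups of 4 arrays 1 array lay far from the other 3, where about 1 in 20, or 34.2, are expected by chance over the 156 genes and 15 lists looked at. In ZD 8 the log2 signals were *Npy* 10.00, *Gpr37l1* 10.98, *Rasal2* 10.12 and *Rps6* 13.16. In ZD 9 they were *Atp5po* 12.82, *Cldn5* 11.01 and *Lyz2* 10.40, in ZD 3 *Drc12* 7.73 and *Pmch* 13.29, and in ZD 2 *Irf7* 8.69, *Slc17a6* 12.70 and *Slc30a3* 8.60. Among PF arrays they were *Col1a1* 7.51, *Cyp51* 12.53 and *Stard4* 8.77 in PF 1, *Drc12* 8.38 and *Foxj1* 8.62 in PF 2, *Gpr37l1* 10.77, *Higd1b* 8.00, *Slc30a5* 9.35 and *Slc39a11* 8.90 in PF 4, and *Slc39a10* 11.06 in PF 6. Among ZRPF arrays they were *Hcrt* 10.31 in ZRPF 2, *Atp1b2* 12.64 in ZRPF 4, *Kpna1* 8.97 in ZRPF 5, and *Col1a1* 8.19 and *Pspc1* 10.39 in ZRPF 6. Among ZR arrays they were *Nr1d1* 7.92 in ZR 7, *Cldn10* 10.67 and *Mx2* 8.20 in ZR 10, *Hspa1a* 7.10 and *Zfp74* 8.45 in ZR 13, and *Cartpt* 11.22 and *Dhcr7* 9.82 in ZR 15. Of the lists, cholesterol synthesis had a mean deviation of 0.051 in ZD 3 and ependyma and tanycyte markers of 0.11 in ZRPF 2.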

How the results depend on the processing

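Alternatives chosen after the data were seen were leaving out ZD arrays 8 and 9 together, the covariates for lists, and all those of the lists on the interaction. With 4 arrays per group part of the smaller changes is missed, and dim transcripts below the filter were not tested. In the simulation 49 of 67 log2 changes of 0.5 were found. That share came from independent noise, with larger changes simulated beside them that loosen the adjusted threshold. It does not give the share found in the real arrays. ZD against PF gave 0 probe sets under each alternative that kept all arrays of its groups, 1 without ZD arrays 8 and 9, and 0 to 3 with single arrays left out. ZR against ZRPF gave 0 with quantile normalization, no filter, the brightest 10348 probe sets, no intensity trend, the Gapdh covariate and its own 8 arrays, and 0 to 9 with single arrays left out. The brightest 10348 do not include *Clstn3*, and for the others the cause was not tested. The interaction gave 0 to 1. ZRPF against PF gave 1465 with choroid plexus and thalamus covariates, 771 with the Gapdh covariate, 1573 with probe sets averaged per gene (a count of genes), 1085 with rat number as a block on 6 arrays and 1305 on the same 6 arrays without the block (fewer arrays), and 1681 to 2264 with single arrays left out. Its calls were higher in ZRPF in 60.7% of cases, 55.8% with quantile normalization and 31.2% with median centring. The correlation between experiments was -0.025 with no filter and -0.0051 over the brightest 10348 probe sets. Lists called numbered 0 in each comparison with an estimated correlation. ZD against PF gave 5 with choroid plexus and thalamus covariates, and 7 to 13 with single arrays left out. In the former these 2 lists were tested with their own means as covariates, so they could hardly pass. ZR against ZRPF gave 3 with quantile normalization and 2 to 9, the interaction 4 to 10, and ZRPF against PF 5 with quantile normalization and 2 to 4. Directions reversed for *Slc39a3* between ZD and PF with probe sets averaged (0.17), *Avp* without ZD array 8 (0.091, and -0.67 without ZD array 9) and *Ndufb8* without ZD arrays 8 and 9 (-0.042). A further 50 sign changes in 14 genes, whose change was within its standard error and below the threshold, were counted as no change. Of the named genes' other values 3967 kept direction and side of the threshold, 13 lost and 6 gained a call. Where no cause is given, it was not tested.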

Other observations

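Tests of the mean of both experiments, of list means by exact permutation and of lists by fry on the interaction were chosen after the data were seen.

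*RT1-S3*, an MHC class I gene, was higher in zinc-deficient and in recovered rats alike. On its 3 tested probe sets the log2 change was 0.64, 0.81 and 0.92 between ZD and PF and 0.63, 0.76 and 0.75 between ZR and ZRPF, with all 4 arrays above all 4 controls in both experiments on each. In neither experiment alone did it pass (smallest adjusted p 0.151 and 0.927). For the mean of both changes, 3 of 15521 probe sets passed in limma: *RT1-S3* on 2 probe sets (0.79 ± 0.13 and 0.83 ± 0.14, SE) and *Lrrn3* (-0.40 ± 0.07), each with an adjusted p of 0.0474. No regrouping of arrays, left-out array or other processing was tried on this contrast, so chance cannot be excluded for these calls. The remaining tested *RT1-S3* probe set stood at 0.63 (adjusted p = 0.0711). Another, below the filter, was higher by 0.63 and 0.57, with 4 of 4 ZD arrays above all PF arrays and 2 of 4 ZR arrays above all ZRPF arrays. Probe sets of MHC class I genes share sequence with related genes. *C1qtnf12* (0.60), *Cryab* (-0.59), *Galnt1* (-0.30), *Per2* (-0.30) and *Gpd1* (-0.66) came next and did not pass (adjusted p from 0.251 to 0.527). The genes of this contrast were named after their values in it were seen. *RT1-S3*, *Lrrn3*, *Cryab*, *Galnt1* and *Gpd1* had also been named by the fixed rule in a single comparison.

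Ependyma and tanycyte markers had a mean deviation of -0.14 ± 0.07 (SD, n = 4) in PF, 0.06 ± 0.05 in ZD, 0.13 ± 0.01 in ZRPF and -0.04 ± 0.05 in ZR. Their change was higher in 9 of 9 members between ZD and PF than between ZR and ZRPF, and by fry the interaction had an adjusted p of 7.34e-05, against 0.0634 by camera with an estimated correlation. With no filter the difference was 0.07 instead of 0.37 (adjusted p = 0.0814 by camera) and the change between ZD and PF 0.01 instead of 0.20. Fry also gave an adjusted p of 1.54e-05 between ZRPF and PF for this list, 0.00135 for hypothalamus markers, and 0.0178 each for cholesterol synthesis and for GABA and glutamate receptors. Camera did not call the ependyma list (adjusted p = 0.0977, and 0.497 with an estimated correlation) or the GABA and glutamate receptors (0.276 and 0.9) between ZRPF and PF. The exact two-sided permutation p of the ependyma list means was 0.0286, the smallest 4 against 4 arrays can give, in both ZD against PF and ZR against ZRPF (adjusted 0.324 and 0.486). Carbonic anhydrases had the same p between ZD and PF, thyroid hormone targets between ZR and ZRPF, and 8 lists between ZRPF and PF.

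Lists not described so far did not pass by camera between ZD and PF. Adjusted p was 0.163 for feeding receptors, 0.168 for carbonic anhydrases, 0.199 for striatum markers, 0.235 for ribosomal proteins, 0.256 for midbrain markers, 0.521 for salt and water balance, for GABA and glutamate receptors, for pituitary markers and for oligodendrocyte precursors, and 0.545 for astrocyte markers and for fasting and insulin signalling. It was 0.69 for opioid and dopamine signalling, oligodendrocytes and respiratory chain subunits, 0.789 for hypothalamus markers, 0.801 for antioxidant genes, 0.897 for immediate early genes, 0.915 for cortex and hippocampus markers, 0.917 for the circadian clock and 0.958 for thyroid hormone targets. Of 21 tested clock genes 10 were higher and 11 lower in ZD, so a test for a shift one way has little to find. Fry's test for changes in either direction gave this list an unadjusted p of 1.61e-05. That p was not adjusted over the lists, and it was not compared with regrouped arrays. Adjusted over the list alone, 3 clock genes were higher and 1 lower in ZD.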
